A study of Homo sapiens with 12 samples.

How the data were processed

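RNA was measured by sequencing in 12 libraries of HK-2 cells, an immortalised human line of proximal tubule epithelium from the kidney. Per the labels, cells were treated for 48 h with recombinant S100A8, S100A9 or S100A8/S100A9 at 5 mg/mL or with phosphate-buffered saline (PBS) as control, with 3 libraries in each of the 4 groups. The dose is copied from the labels, and its unit could not be checked against another source. The labels do not say that replicates came from separate cultures, so all p-values measure only the spread between these samples, which may be technical.

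The authors deposited 1 table of genes for all libraries. Per the file headers it holds a count and an FPKM value, which is scaled to gene length and library total, for each gene and library. The deposited counts are expected counts, that is estimated reads that need not be whole: 12.0% of the entries were not whole numbers. FPKM values are the authors' own normalization for gene length and depth. The aligner, the counting tool and the annotation are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, whereas all 20286 gene IDs in the table are human Ensembl IDs. The build behind the counts is therefore not known, and coordinates given here come from GENCODE release 29 on GRCh38. Of the gene IDs, 19717 were named through a table of gene names, 521 through GENCODE and 48 had no name. Some symbols stood for more than 1 ID, among them SOD2 and HERC3, and these IDs were tested apart.

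Library totals ranged from 15882193 to 20748334 counts. A gene with 0 counts could have held up to 3 counts, which is 0.189 CPM (counts scaled to library totals) in the smallest library and 0.145 CPM in the largest. Such floors cover counting error only, because the reads were not reported to carry molecular identifiers.

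Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10), which left 13512 genes, and libraries were scaled by TMM. A quasi-likelihood model with the robust option was fitted to all 12 libraries with 1 coefficient per group and no block, so that the groups shared an estimate of the spread on 8 residual degrees of freedom. The common biological coefficient of variation was 4.65%. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested within a comparison and a threshold of 0.05. Standard errors (SE) were derived from the quasi-likelihood statistic and 95% intervals from its t distribution. Levels are TMM-normalised CPM, given as mean ± SD over 3 libraries. The 3 treated arms were each compared with control and with each other.

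Named genes followed a rule set before the data were examined. For each arm against control it took up to 6 rising and 6 falling genes by size of log2 fold change, among those past the threshold with a mean of at least 1 CPM and all 3 treated libraries beyond all 3 controls. It added up to 3 members of each list past the threshold, and S100A8, S100A9, TLR4 and AGER in any case. Between arms it took 3 genes per direction, and where no gene passed it took the 3 with the smallest p per direction. Other genes named in the text were chosen after their values were seen. A gene that the rule took is not reported here.

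For gene groups, 32 lists were fixed before the data were examined and tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and, beside it, with an estimated correlation. Adjustment was over the lists within a comparison. Counts of list members were made with adjustment over all genes and adjusted over the list alone.

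Alternatives set beforehand were the replicate number as a block, size factors of DESeq2, no filter on low counts, the Wald test of DESeq2 1.42.0, fits on only the 6 libraries compared, a minimum change of 2-fold and leaving out each library in turn. Those chosen after seeing the data were limma on log2(FPKM + 1), a fit without the robust option, counts thinned to the smallest library, summed counts of C4A with C4B and of SAA1 with SAA2, and S100A9 against the other 9 libraries pooled. Because 3 comparisons share the same control libraries, unchanged groups were simulated against them 50 times. For the direct tests of genes selected in S100A9 against control, all 12 libraries were simulated without change 50 times and fitted in the same way. The procedure was tested on simulated data with 50 genes changed at each fold size. In S100A9 against control, over 13418 genes, it recovered 64% of genes changed by 1.25-fold and 88% of those changed by 2-fold. There 0 were called in the wrong direction, and 9 of 178 calls were of unchanged genes. In S100A8/S100A9 against control the shares recovered were 50% and 92%, with 12 of 169 calls of unchanged genes. In S100A8 against control they were 56% and 86%, with 8 of 165. The simulated arms held many more changed genes than were called in the real ones, and no structure of the samples. The shares recovered may therefore be too high for the real arms. Pairs of libraries within a group were checked for duplicates by chi-square on genes with at least 20 counts, and gave between 2.36 and 5.46 per gene, above sampling noise in each pair. No library was left out.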

Results

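Expression was measured in HK-2 proximal tubule cells after 48 h with recombinant S100A8, S100A9 or S100A8/S100A9 at 5 mg/mL as the labels print it, a dose whose unit could not be checked, or with PBS. S100A8 and S100A9 are calcium-binding proteins of myeloid cells that pair into the heterodimer known as calprotectin. Each of the 4 groups held 3 libraries, with totals of 15882193 to 20748334 counts and between 15483 and 15653 genes above 0 counts. Transcripts of the added proteins were not detected: S100A8 and S100A9 had 0 counts in all 12 libraries, as did the related S100A12, which was not added. A count of 0 allows up to 0.189 CPM in the smallest library. The receptor genes TLR4 and AGER were low in control cells, at 2.73 ± 0.54 and 2.46 ± 0.35 CPM (SD, n = 3). Neither passed the test in any arm. The log2 difference of TLR4 from control was 0.23 (95% interval -0.21 to 0.67) after S100A8, -0.04 (-0.48 to 0.41) after S100A9 and 0.18 (-0.26 to 0.61) after S100A8/S100A9.

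S100A9 alone was compared with PBS to ask which transcripts differ after this subunit. LCN2, which encodes the iron-siderophore-binding protein NGAL and is a marker of tubular injury, rose from 6.25 ± 2.32 to 54.9 ± 18.9 CPM, a log2 fold change of 3.15 (SE 0.33, adjusted p = 0.0091). The acute-phase genes SAA2 and SAA1 rose by 2.77 (SE 0.43) and 2.66 (SE 0.32) on the log2 scale. Chemokine CCL20 rose by 2.37 (SE 0.33), CSF2, which encodes the growth factor GM-CSF, by 1.48 (SE 0.17), the neutrophil chemoattractant CXCL8 by 1.33 (SE 0.10) and the cytokine IL6 by 1.30 (SE 0.13). The gene with the smallest p was SOD2, the mitochondrial superoxide dismutase, which went from 288 ± 5.26 to 512 ± 22.8 CPM (log2 fold change 0.83, SE 0.04, adjusted p = 2.1e-13).

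In all, 20 of 13512 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment after S100A9, 19 higher and 1 lower, and 9 of them by at least 2-fold. For each gene named here, all 3 treated libraries lay beyond all 3 controls. Complement gene C3 rose from 84.7 ± 4.90 to 179 ± 22.4 CPM (log2 fold change 1.08, SE 0.10). NFKBIA, the inhibitor that NF-kB itself induces, rose by 0.30 (SE 0.06), and the metallothionein MT2A by 0.30 (SE 0.05). The gene that fell was F2R, a thrombin receptor, with a log2 fold change of -0.20 (SE 0.04, adjusted p = 0.034). Chosen after their values were seen, the other genes that rose were CXCL2 (1.04), CLEC4E (0.73), PDZK1IP1 (0.66), the RNase gene ZC3H12A (0.61), ITGA1 (0.42), ELF3 (0.32), ZC3H12C (0.28) and WWC1 (0.21).

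SAA1 and SAA2 are near-identical, and reads could be split between them. Summed, the pair rose from 0.730 ± 0.128 to 4.82 ± 0.141 CPM, a log2 fold change of 2.71 (SE 0.28, adjusted p = 1.4e-06 in edgeR's quasi-likelihood test). SOD2 is represented by 2 IDs. The values here are of ENSG00000112096, on chromosome 6 from 159669057 to 159745186, while the other lay at 0.490 CPM in control cells and did not pass the test. LCN2 (ENSG00000148346) lies on chromosome 9 from 128149071 to 128153455, CXCL8 (ENSG00000169429) on chromosome 4 from 73740506 to 73743716 and C3 (ENSG00000125730) on chromosome 19 from 6677704 to 6730562.

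**Figure D1:**
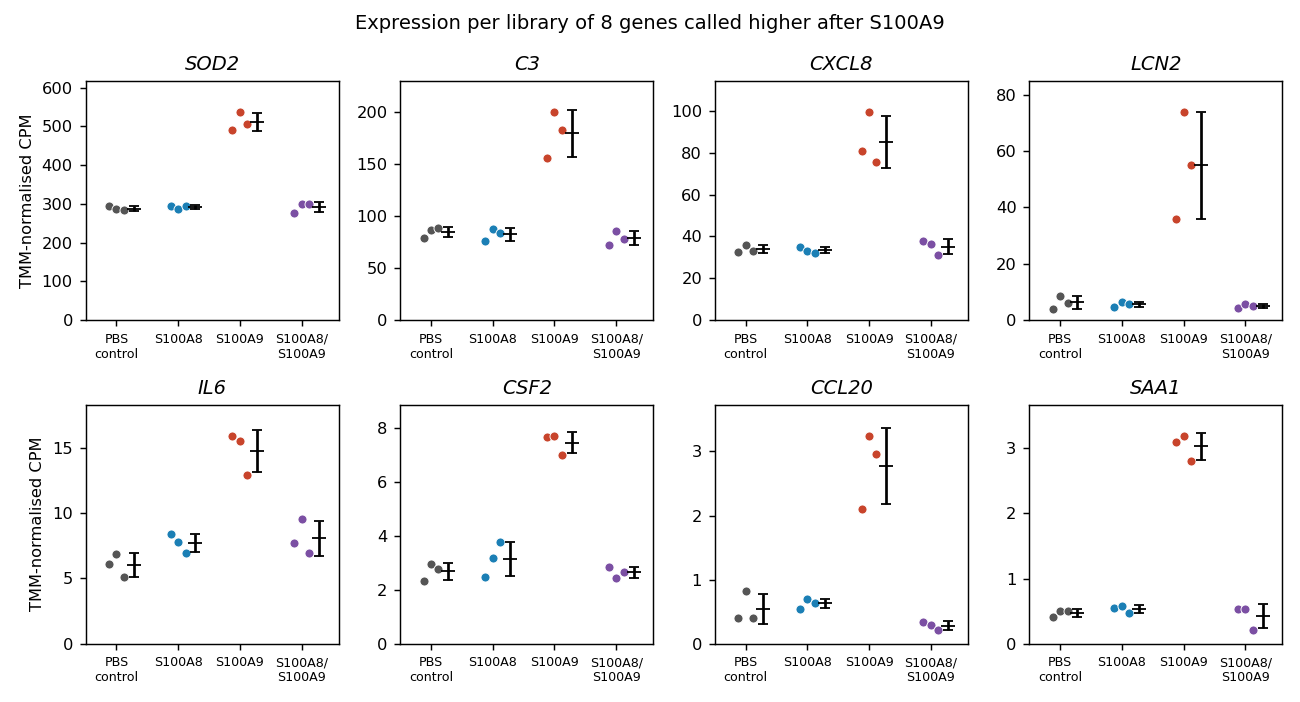
TMM-normalised CPM (linear axis from 0) of 8 genes higher after S100A9, by group; each point is a library, and the bar at its right is the mean with the SD of 3 libraries. The S100A9 libraries lie above the 9 other libraries for each of these genes; for SOD2 the group means are 288 CPM in control, 292 after S100A8, 512 after S100A9 and 292 after S100A8/S100A9.

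Among 21 tested cytokine and chemokine genes, 5 rose after S100A9 (CCL20, CSF2, CXCL2, CXCL8, IL6), 0 fell and 16 did not pass the test; adjusted over the list alone, 7 rose, which added CXCL5 and CSF1. As a set the list was higher (camera adjusted p = 5.3e-09), and remained so at adjusted p = 0.0040 with an estimated correlation. Of 15 complement and acute-phase genes, 4 rose (C3, LCN2, SAA1, SAA2), 0 fell and 11 did not pass. Adjusted over the list alone, 6 were higher and 3 lower; the set was higher at adjusted p = 0.00015, and adjusted p = 0.105 with an estimated correlation. Of 27 NF-kB target IDs, 2 rose (SOD2, NFKBIA), 0 fell and 25 did not pass; adjusted over the list alone, 8 were higher, among them TNFAIP2 at 0.22 and IER3 at 0.20, and 1 lower. The NF-kB set was higher at adjusted p = 2.5e-05, and adjusted p = 0.170 with an estimated correlation. Among 23 tubular injury markers 1 rose, LCN2, and the set was not past the threshold (camera adjusted p = 0.814). Adjusted over the list alone, 1 was higher, LCN2, and 2 were lower, PLIN2 and CD24.

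Several sets of housekeeping genes were higher after S100A9 by small amounts with the preset correlation of camera, and none of them passed with an estimated one. The 66 nuclear genes of oxidative phosphorylation had a median log2 fold change of 0.07, with 58 above 0, and the 77 ribosomal protein genes a median of 0.07, with 60 above 0. All 13 mitochondrially encoded genes lay above 0, with a median of 0.10. Of these 3 lists 0 members passed edgeR's test over all genes, where 791 genes had an unadjusted p under 0.05, and adjusted over the list alone 2 ribosomal protein genes rose (RPL34, RPS21). The preset-correlation tests gave adjusted p = 5.3e-09, 1.6e-08 and 2.5e-05, and adjusted p = 0.200, 0.308 and 0.308 with an estimated correlation. The p53 targets (30 genes, median 0.04, adjusted p = 0.026) and the metallothionein and zinc transport genes (11 genes, median 0.04, adjusted p = 0.034) were also higher, and adjusted p = 0.308 and 0.304 with an estimated correlation. Of the metallothionein list 1 gene rose, MT2A, and 3 adjusted over the list alone. Epithelial junction and keratin genes (29 genes, median -0.05) were lower at adjusted p = 0.027, and adjusted p = 0.202 with an estimated correlation; 0 passed over all genes and 2 adjusted over the list alone, KRT7 and CDH6.

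The count of 20 became 42 with the replicate number as a block, 9 with a minimum change of 2-fold and 13 with limma on log2(FPKM + 1). It became 12 without control replicate 1, 11 without control replicate 2 and 13 without S100A9 replicate 3, while SOD2, CCL20, C3, SAA1, SAA2, IL6, PDZK1IP1, CSF2 and CXCL8 passed the threshold in each of 6 fits with a library left out. ZC3H12A passed in 5 of the 6, LCN2 (highest adjusted p = 0.059 in edgeR), WWC1 and ITGA1 in 4, CXCL2, NFKBIA, MT2A, ZC3H12C and F2R in 2, and ELF3 and CLEC4E in 1.

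S100A8 alone was compared with PBS in the same way. A single gene passed, the complement gene C4B (ENSG00000224389, chromosome 6 from 32014795 to 32035418), at 0.317 ± 0.228 CPM against 2.14 ± 0.864 in control (log2 fold change -2.73, SE 0.45, adjusted p = 0.033 in edgeR's quasi-likelihood test). C4B has a near-identical neighbour, C4A, which stood at 3.35 ± 0.487 CPM after S100A8 and 1.94 ± 0.581 in control, a log2 difference of 0.79 (SE 0.26, unadjusted p = 0.0054 in edgeR, adjusted p = 1.00). Summed over both genes, the level was 3.67 ± 0.493 CPM after S100A8 and 4.07 ± 0.733 in control, with a log2 difference of -0.15 (95% interval -0.53 to 0.24). In that fit 0 genes passed edgeR's test, so no call remained once the reads of both genes were summed; in the fit with both genes apart 477 genes had an unadjusted p under 0.05, against 676 expected by chance, and DESeq2 called 1 gene and limma 0.

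Of the genes that rose after S100A9, the median log2 difference from control after S100A8 was 0.02 over 19 genes, with a range from -1.08 (SAA2, 95% interval -2.56 to 0.41) to 0.42 (CXCL2, 0.04 to 0.79). SOD2 differed from control by 0.02 on the log2 scale (95% interval -0.06 to 0.10), CXCL8 by -0.02 (-0.25 to 0.21) and C3 by -0.04 (-0.26 to 0.18). Of 48 genes of mitosis and G2/M, 45 lay above 0, with a median of 0.09; 0 passed edgeR's test over all genes, and 5 rose adjusted over the list alone (PTTG1, NUF2, CDK1, MKI67, CKAP2L). The set was higher at adjusted p = 7.7e-16, and adjusted p = 0.122 with an estimated correlation. Oxidative phosphorylation genes (66, median 0.05) and ribosomal protein genes (77, median 0.03) were also higher as sets, at adjusted p = 0.0012 and 0.0056, and adjusted p = 0.857 and 0.967 with an estimated correlation. Complement and acute-phase genes (15, median -0.05) and cytosolic heat shock genes (22, median -0.05) were lower, both at adjusted p = 0.021, and adjusted p = 0.513 and 0.857 with an estimated correlation. Of these last 4 lists 0 members passed edgeR's test over all genes, and 1 adjusted over the list alone, the complement protease-like gene C1RL, which was lower. The count of 1 fell to 0 on the 6 libraries compared alone, in the fit without the robust option, and without control replicate 2, S100A8 replicate 1 or S100A8 replicate 2; it was 2 with the replicate number as a block and without control replicate 1.

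The third arm, S100A8/S100A9, was compared with PBS to ask what the combined preparation does. By edgeR's quasi-likelihood test 0 genes passed, with a smallest adjusted p of 0.63; 757 genes had an unadjusted p under 0.05 against 676 expected by chance, DESeq2 called 1 gene and limma on log2(FPKM + 1) called 0. Among the lowest p in each direction were those of DPY19L2 (log2 difference -0.37, SE 0.08), COL7A1, a collagen of anchoring fibrils (-0.20, SE 0.05), and an ID named HERC3 (ENSG00000287542, -1.68, SE 0.39, at 0.592 CPM against 1.95), and of RNF169 (0.27, SE 0.07) and the mitotic gene DLGAP5 (0.19, SE 0.05). A second ID named HERC3 lay at 11.7 CPM in control cells and differed by 0.09. SOD2 differed from control by 0.02 (95% interval -0.06 to 0.10), CXCL8 by 0.05 (-0.17 to 0.27) and LCN2 by -0.32 (-1.32 to 0.68).

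Of the 48 mitotic genes, 45 lay above 0 after S100A8/S100A9, with a median of 0.07, and 7 rose adjusted over the list alone, among them DLGAP5, TOP2A and PTTG1, but 0 in edgeR's test over all genes. The set was higher at adjusted p = 1.6e-11, and adjusted p = 0.286 with an estimated correlation. Mitochondrially encoded genes (13, all above 0, median 0.11) and oxidative phosphorylation genes (66, median 0.03) were higher, at adjusted p = 8.7e-06 and 0.019, and adjusted p = 0.507 and 0.806 with an estimated correlation. Complement and acute-phase genes (15, median -0.11) were lower at adjusted p = 0.019, and adjusted p = 0.440 with an estimated correlation. That list was also lower after S100A8, but both comparisons use the same control libraries and are not independent. Of these 3 lists 0 members passed edgeR's test over all genes; adjusted over the list alone MT-ND1 was higher and C1RL lower. The gene count was 2 with the replicate number as a block, 2 on the 6 libraries compared alone and 2 without control replicate 1.

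**Figure D2:**
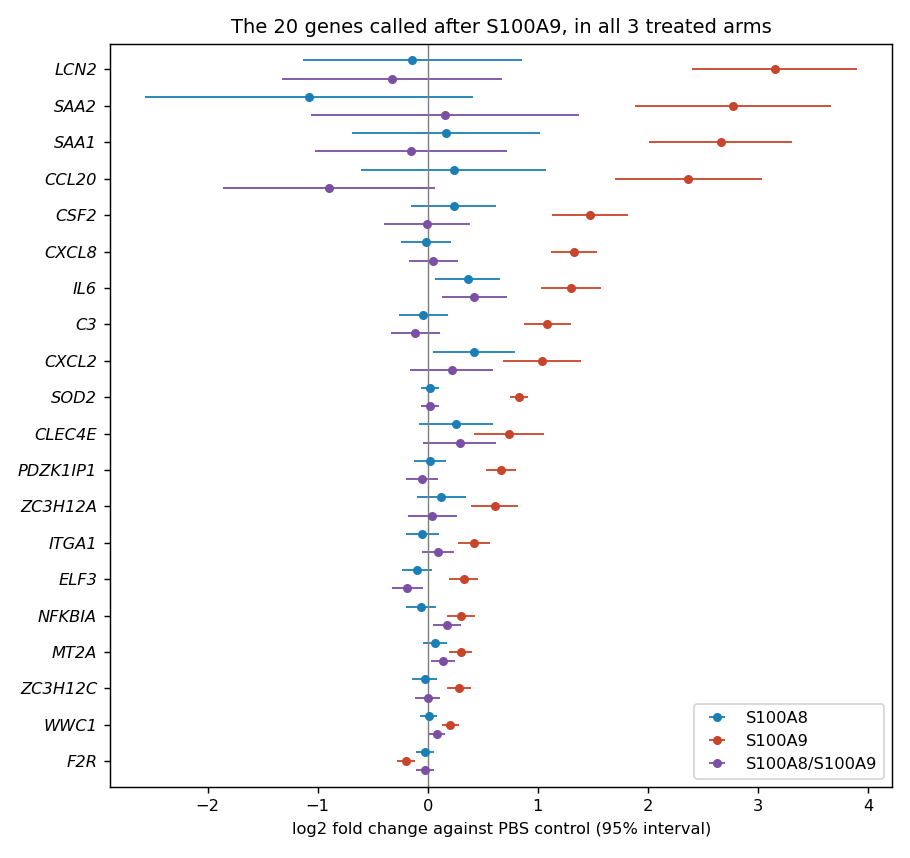
Log2 fold change against PBS control, with 95% intervals, of the 20 genes past the threshold after S100A9, in each of the 3 treated arms. For the 19 genes that rose, the median in S100A8 is 0.02 and in S100A8/S100A9 0.04.

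The arms were then compared directly. The preparation labelled S100A8/S100A9 names both subunits, and it was first set against S100A9 alone. LCN2 was 5.00 ± 0.792 CPM after S100A8/S100A9 and 54.9 ± 18.9 after S100A9, a log2 fold change of -3.47 (95% interval -4.23 to -2.71, adjusted p = 0.0046). CCL20 differed by -3.26 (-4.00 to -2.53) and SAA1 by -2.81 (-3.46 to -2.16). SOD2 differed by -0.81 (-0.89 to -0.73, adjusted p = 3.4e-13). Higher in S100A8/S100A9 than in S100A9 were ID2, an inhibitor of helix-loop-helix factors (0.32, SE 0.07), the keratin KRT7 (0.25, SE 0.05) and the surface glycoprotein gene CD24 (0.23, SE 0.04).

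In this comparison 34 genes passed edgeR's quasi-likelihood test, 4 higher and 30 lower. Among cytokines 5 of 21 were lower and 10 adjusted over the list alone (set adjusted p = 1.1e-09, and adjusted p = 0.0028 with an estimated correlation), and among complement and acute-phase genes 5 of 15 were lower and 7 adjusted over the list alone (adjusted p = 9.2e-09, and adjusted p = 0.010 with an estimated correlation). A further 8 sets passed with the preset correlation and 0 of these 8 with an estimated one, for which the smallest adjusted p was 0.115; by median, NF-kB targets (-0.10), p53 targets (-0.08), ribosomal proteins (-0.06), oxidative phosphorylation (-0.05) and heat shock genes (-0.04) were lower, and mitotic genes (0.06), mesenchymal genes (0.05) and TGF-beta targets (0.05) higher. The count of 34 was 71 with the replicate number as a block, 7 with a minimum change of 2-fold and 13 with limma on log2(FPKM + 1). It was 16 without S100A9 replicate 2, 15 without S100A9 replicate 3, 14 without S100A8/S100A9 replicate 1 and 19 without S100A8/S100A9 replicate 3.

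S100A9 was also set directly against S100A8. LCN2 was higher after S100A9 by 3.29 on the log2 scale (95% interval 2.53 to 4.05, adjusted p = 0.0063), SAA1 by 2.50 (1.86 to 3.13) and CCL20 by 2.13 (1.48 to 2.78). Lower after S100A9 were ID2 (-0.35, SE 0.07) and the helicase gene DDX60L (-0.29, SE 0.06). In all, 25 genes passed edgeR's quasi-likelihood test, 23 higher and 2 lower; 1 of the 23 was C4B. With C4A and C4B summed that call ended and the direction turned, with a log2 difference of -0.15 (95% interval -0.54 to 0.25).

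Of 21 cytokine genes 4 were higher after S100A9 than after S100A8 and 9 adjusted over the list alone (adjusted p = 1.8e-09, and adjusted p = 0.0033 with an estimated correlation), and of 15 complement and acute-phase genes 5 were higher and 7 adjusted over the list alone (adjusted p = 2.5e-08, and adjusted p = 0.013 with an estimated correlation). Interferon response genes (33, median -0.07) were lower at adjusted p = 0.00061, and adjusted p = 0.162 with an estimated correlation. A further 9 sets passed with the preset correlation and 0 of these 9 with an estimated one (smallest adjusted p = 0.091): NF-kB targets, p53 targets, heat shock, oxidative phosphorylation, mitochondrially encoded, ribosomal protein and metallothionein genes were higher, and TGF-beta targets and mitotic genes lower. The count of 25 was 69 with the replicate number as a block, 8 with a minimum change of 2-fold and 10 with limma on log2(FPKM + 1). It was 14 without S100A8 replicate 2 and 14 without S100A9 replicate 3.

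Taking the 19 genes that rose after S100A9, 16 were lower in S100A8 than in S100A9 by the direct test, 15 were lower in S100A8/S100A9 than in S100A9, and 14 were lower in both. Both direct tests use the S100A9 libraries in which the 19 genes were selected, so these counts are not independent of the selection. In 50 simulations of 12 libraries without change, the 19 rising genes of smallest p were taken whether or not they passed the threshold. On average 0.24 rising genes passed it there (at most 2). The mean number lower in both after adjustment was 0.04 (at most 1), a low value to be foreseen where no gene changes. At an unadjusted p under 0.05 it was 3.68 (at most 8), against 19 observed. The simulations follow the fitted model and hold no structure of the samples. They also hold no changed genes, so they do not gauge how the selection affects the direct tests of genes that did change. The 14 were C3, CCL20, CSF2, CXCL8, ELF3, IL6, ITGA1, LCN2, PDZK1IP1, SAA1, SAA2, SOD2, ZC3H12A and ZC3H12C. CLEC4E and MT2A passed neither direct test. The 95% interval against control lay above 0 for IL6 in both other arms, with log2 differences of 0.36 (0.06 to 0.66) after S100A8 and 0.42 (0.13 to 0.72) after S100A8/S100A9, although neither passed after adjustment (adjusted p = 1.00 and 0.77 in edgeR). It also lay above 0 for CXCL2 after S100A8, and for NFKBIA (0.17), MT2A (0.14) and WWC1 (0.08) after S100A8/S100A9, none of which passed after adjustment. These differences use the control libraries against which the 19 genes were selected. Low values in those controls would raise them in both arms. ADAMTS9, CFB and GDF15, chosen after their values were seen, passed both direct tests but not the test of S100A9 against control.

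Between S100A8/S100A9 and S100A8, 0 genes passed edgeR's quasi-likelihood test; 598 had an unadjusted p under 0.05 against 676 expected by chance, DESeq2 called 1 gene and limma on log2(FPKM + 1) called 0. The difference was 0.00 for SOD2 (95% interval -0.08 to 0.08), 0.07 for CXCL8 (-0.16 to 0.29) and -0.07 for C3 (-0.29 to 0.15), while for LCN2 it was -0.18 with a wide interval of -1.20 to 0.84. The 3 smallest p values in each direction belonged to C4B (2.33, SE 0.46), TM4SF19-DYNLT2B (1.87, SE 0.44), the pregnancy glycoprotein gene PSG3 (0.75, SE 0.20), RGPD1 (-0.58, SE 0.15), the mismatch repair family gene MSH5 (-0.51, SE 0.13) and IGFN1 (-0.28, SE 0.06), of which PSG3 and RGPD1 have close paralogs that could share reads. Summed with C4A, the difference of C4B became -0.10 (95% interval -0.50 to 0.29). The 13 mitochondrially encoded genes all lay above 0 (median 0.11) and 7 rose adjusted over the list alone; the set was higher at adjusted p = 1.7e-06, and adjusted p = 0.794 with an estimated correlation.

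**Figure D3:**
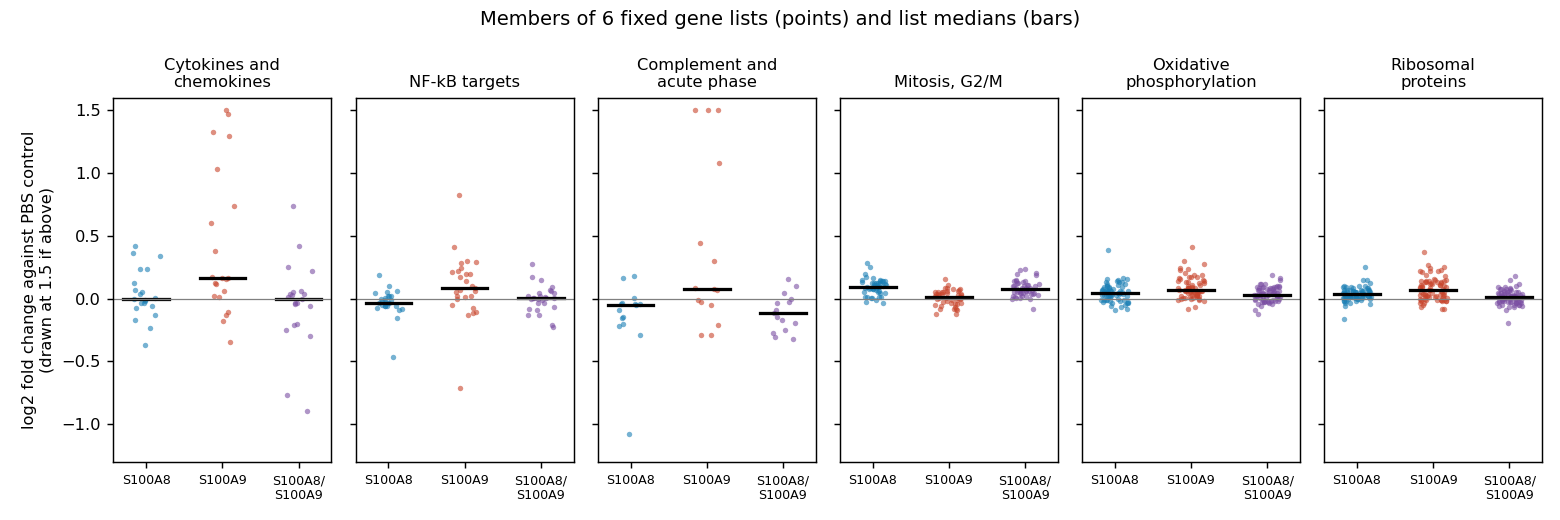
Log2 fold change against PBS control of each tested member of 6 gene lists (points) and the list median (bar) in the 3 treated arms; values above 1.5 are drawn at 1.5. Cytokine and chemokine genes have a median of 0.16 after S100A9 and -0.01 in both other arms, and mitotic genes a median of 0.09 after S100A8, 0.01 after S100A9 and 0.07 after S100A8/S100A9.

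The 3 comparisons with control share its 3 libraries, which makes their fold changes correlate without any effect. Across 13512 genes, which are not independent replicates, the correlation was 0.437 between S100A8 and S100A9, 0.513 between S100A8 and S100A8/S100A9 and 0.470 between S100A9 and S100A8/S100A9. Unchanged groups simulated against the same controls gave means of 0.460, 0.460 and 0.468. The covariance exceeded the simulated one by 0.00265, 0.00474 and 0.00352, beside simulated SDs of 0.000902, 0.00103 and 0.000869. However, the simulated groups were drawn around the mean of all 12 libraries, the controls included. That places them nearer to these controls than unchanged groups would lie and makes the simulated values too low. The excess therefore cannot be read as a shared response. With at most 1 call in each of the other arms, an overlap of calls with S100A9 could not be informative. With 3 controls the group could not be divided into parts of at least 2, so the values could not be given again with separate controls, and part of any excess in correlation may come from the shared controls.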

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

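Chosen only after the results were seen were the fits on FPKM, without the robust option, on thinned counts, on summed paralogs and on S100A9 against the other 9 libraries. Among the named genes and lists past the threshold, no direction reversed in the fits that kept paralogs apart. Reversals among those not past it were not counted. With C4A and C4B summed, C4B's higher level turned to -0.15 in S100A9 against S100A8 and to -0.10 in S100A8/S100A9 against S100A8. The 20 genes of S100A9 against control became 42 with the replicate block, 9 at 2-fold, 13 by limma on FPKM, 16 on the 6 libraries alone (14 of the 20 among them), 47 against the pooled 9 libraries (18 of the 20 among them) and 11 to 22 with a library left out. The 1 gene of S100A8 against control became 2 with the replicate block, 0 on the 6 libraries alone, 0 by limma on FPKM, 0 without the robust option, 0 with paralogs summed (C4B merged into C4A) and 0 to 2 with a library left out. The 0 of S100A8/S100A9 against control became 2 with the replicate block, 1 by DESeq2, 2 on the 6 libraries alone and 0 to 2 with a library left out; the 0 against S100A8 became 1 by DESeq2. The 34 of S100A8/S100A9 against S100A9 became 71 with the replicate block, 7 at 2-fold, 13 by limma on FPKM, 33 on the 6 libraries alone (30 shared) and 14 to 31 with a library left out. The 25 of S100A9 against S100A8 became 69 with the replicate block, 8 at 2-fold, 10 by limma on FPKM, 22 on the 6 libraries alone (19 shared) and 14 to 24 with a library left out. Of 24 calls of named genes, 10 were lost on the 6 libraries alone, 9 at 2-fold, 4 without the robust option and 1 by DESeq2. On thinned counts 3 were lost (NFKBIA in S100A9 against control, ID2 in S100A8/S100A9 against S100A9, DDX60L in S100A9 against S100A8). By limma on FPKM 8 of the 23 such calls tested there were lost. Apart from the summed genes and the stricter threshold, the cause was not tested. Replicate numbers did not meet the criterion for pairing, which asked for each correlation to pass 0.1: 2 of 18 same-number pairs had a correlation of deviations above it (median 0.05). The median of the 36 other pairs was -0.01. A weaker structure by replicate number could fail so strict a criterion. There were hints of a structure by number. For 8 of 12 libraries, the mean correlation with libraries of the other groups was highest for their own number. On the first principal component replicate 1 lay at or above 4.41 and replicate 2 at or below -2.77 in all 4 groups. Of 41 list calls, 36 were lost with an estimated correlation, 5 without the filter on low counts and 3 with the replicate block (epithelial junction genes in S100A9 against control, metallothionein genes in S100A9 against control and against S100A8), where 2 others passed. The block also lost 1 of the 24 gene calls, MT2A in S100A9 against control. Low counts limit several genes, among them SAA2, CCL20 and C4B, at under 3 CPM in each group. SAA1 was also low, at 0.473 CPM in control and 3.03 after S100A9. Of the genes named but not called, AGER, TM4SF19-DYNLT2B and HERC3 (ENSG00000287542) lay under 3 CPM in each group too.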

Other observations

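The tests for leukocytes, for the content of the S100A8/S100A9 preparation, for the mitotic list and for S100A9 against 9 pooled libraries were chosen only after the result was seen, and so were the spreads required for the tests of leukocytes, gene length and the mitotic list. S100A9 was set against the other 9 libraries as 1 group, which gave 47 genes by edgeR's quasi-likelihood test, 39 higher and 8 lower. Among the genes that joined were the neutrophil chemokine CXCL5 (log2 fold change 0.69), the macrophage growth factor CSF1 (0.21), the complement gene CFB (0.61), the protease inhibitor SERPINA1 (0.32), the iron storage gene FTH1 (0.18) and the mineralocorticoid receptor gene NR3C2 (0.42). Lower were ID2 (-0.32), KRT7 (-0.21), CD24 (-0.17) and the proximal tubule bicarbonate transporter SLC4A4 (-0.26). Also lower were F2R (-0.18), DDX60L (-0.24), MAP3K14 (-0.26) and ZHX1-C8orf76 (-1.64). Of 220 possible splits of the 12 libraries into 3 and 9, 100 were run: the real one and others drawn at random. Of these 100, 2 gave as many genes, the real one included. The other gave 89, above the real count, and it put together replicate 2 of control, S100A8 and S100A9; the next gave 14. That points to a structure of the samples that follows the replicate number in part, although the labels name no batch.

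A first pattern is the rise after S100A9 of 5 of 21 cytokine genes and of 4 of 15 complement and acute-phase genes, a set at adjusted p = 0.105 with an estimated correlation (camera). Thinning each library to the smallest total gave 19 genes, 18 of them among all 20 called after S100A9. That argues against unequal depth for these calls as a set, although the call of NFKBIA was lost (adjusted p = 0.078 in edgeR). A further test assumed that the S100A8/S100A9 preparation held about 1 part in 2 as much S100A9, with a proportional response. The genes higher after S100A9 would then have risen there by about that share. Over all 19 genes that rose, listed in the pattern or not, the median share of the S100A9 rise was 0.0224 (upper quartile 0.217, ELF3 lowest at -0.474). That argues against such a content for the 19 genes as a set. Such a content stays open for NFKBIA (0.552), MT2A (0.432), WWC1 (0.366) and CLEC4E (0.329). A much lower content would also give a median share this small, so a much lower content stays open for the set, as does a threshold response. In the test for leukocytes in the cultures, 7 leukocyte genes summed to 0.244 CPM more after S100A9 (SE 0.457, here on library totals without TMM). That lay under the bound of 1 CPM by more than 1 SE though not by 2. The rule first used asked for 2 SE under that bound and would have left the question open. The sum was far under the 5.09 CPM that the explanation was taken to need, set from the 50.9 CPM by which CXCL8 rose on the same scale. That argues against leukocytes at such a level. An effect of S100A9 that its partner blocks is a candidate explanation, as is endotoxin or another difference between protein preparations, for which these data hold no test.

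A second pattern is the higher mitotic list after S100A8 and S100A8/S100A9. Low values in the shared controls alone would leave both arms level with S100A9; the smaller of the medians against S100A9 was 0.0562, but with an estimated correlation those contrasts gave adjusted p = 0.099 and 0.120 by camera, so low controls cannot be told apart from a difference of both arms. Members that vary together and were counted as independent remain a candidate explanation for the set call, since the smaller adjusted p with an estimated correlation was 0.122. A small difference in growth or confluence between cultures may also contribute and was not tested.

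Another pattern is the higher ribosomal protein and respiratory chain sets after S100A9, at adjusted p = 0.308 and 0.200 with an estimated correlation (camera). Members that vary together remain a candidate explanation, although the lost calls alone do not show it, as for the mitotic list. After a trend of fold change with exon length was removed, the ribosomal median went from 0.07 to 0.0475 (70.0% kept, bootstrap interval 55.6 to 108%) and the respiratory chain median from 0.07 to 0.0544 (79.3% kept, 59.8 to 112%). The bound set beforehand was that at least 2 parts in 3 be kept, and since both intervals reach below it, a trend with gene length cannot be told apart from other causes here.

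For each comparison the 6 libraries can be split in 10 ways, too few for a share under 0.05. S100A9 against control gave 20 genes and the highest other split 1, so 1 split reached the real count; for S100A8/S100A9 against S100A9 these were 34 and 2, with 1 split, and for S100A9 against S100A8 25 and 1, with 1 split. S100A8 against control gave 1 gene and the highest other split 1, with 2 splits as large. For S100A8/S100A9 the real counts by edgeR were 0 against control (757 genes at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma) and 0 against S100A8 (598, 1 and 0), so all 10 splits were as large; the highest other splits gave 1 and 16 genes. The split with 16 put S100A8 replicate 1 with S100A8/S100A9 replicates 2 and 3, and points to a structure of the samples that the groups do not describe.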
